A study of Mus musculus with 6 samples.

How the data were processed

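RNA was measured in 6 libraries of sorted mouse placental labyrinth endothelial cells, 3 control and 3 knockout. Per the labels, RNA was extracted with the Arcturus PicoPure kit and libraries were made with the SMARTer Ultra-low RNA kit. Samples were assigned to groups from the sample titles, which say wild type or knockout, together with the design text, which describes floxed Dnmt3a with and without Cdh5-Cre; no label states the genotype of a sample. The deposited count table holds raw read counts per Ensembl gene for the 6 libraries and 0 columns of other samples. Per the submitters' processing notes the genome build was GRCm39 and DESeq2 was used, and the aligner, the counting program, the annotation release and the DESeq2 version are not given in the sources used here. The authors also deposited a comparison of knockout with wild type whose columns are, per the file headers, the log2 fold change, its standard error, the p-value and the adjusted p-value. The same table holds a signal column per library, which the authors derived from the raw counts by dividing by 1 size factor per library (checked on the values). That signal was used only to check the order of the count columns. The rule by which the authors kept 15304 of 55536 genes is not given.

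The log2 fold changes and tests reported here were computed from the raw counts, except where the authors' table is named. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16748, and libraries were scaled by TMM. The comparison used the edgeR quasi-likelihood test with group as the only term (edgeR 4.0.16, R 4.3.3), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Abundance is given as CPM on TMM-scaled library sizes. Total counts ran from 40206223 to 44897210 per library, and the biological coefficient of variation was 0.104. Counting error is larger for genes with few counts. The symbols are those of the count table, where 118 genes share a symbol with another gene.

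Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 45 lists with at least 5 measured members. The same lists were tested with an estimated correlation and with fry, whose directional test asks whether the genes of a list move one way on balance. The mixed test of fry asks whether they change in either direction. Counts of members are given over all genes tested and adjusted over the list alone. The gene lists, the tests of genes and lists, the naming rule and the other settings listed next were chosen before the data were examined. Under that rule the text names Dnmt3a, and per direction, among called genes that are not predicted genes and whose groups do not overlap, the 8 with the smallest p and the 4 others with the largest change at a mean of at least 5 CPM. It also names up to 4 members of each list with the smallest p, and up to 3 of the most abundant members of lists of other cell types. Epha5, Pecam1, Kdr, the untested genes, the elastic fibre genes and the protocadherin clusters fall outside it and were chosen after their values were seen.

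The other settings were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, a mean of at least 5 CPM, an absolute log2 fold change of at least 1, the replicate number as a block, and each library left out in turn. For lists they were also an estimated correlation, a prior count of 0.5 and fry. Counts with the genes of chromosome 7 left out, counts with offsets for GC content and transcript length, and list members counted with each library left out were added after seeing the data. The 10 splits of the 6 libraries into 3 and 3 were run through the same fits. Chromosome membership, gene order, GC content and transcript length came from the GRCm38 annotation (GENCODE vM21), which was the mouse annotation available and matched 99.96% of the tested identifiers. Positions are not printed, because the counts were made on another build. Chromosome medians used genes with a mean of at least 10 CPM, each as its deviation from the mean over all libraries. The comparison of chromosomes was not part of the plan made before the data were examined.

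The fit was tested on simulated data with the means, dispersions and library sizes of these samples. In the simulation 200 genes were changed, all above a floor on mean CPM, so recovery of scarcer genes was not measured. After the count filter 16454 simulated genes were tested. Of the changed genes, edgeR recovered 70 of 100 at 1.5-fold and 93 of 100 at 2-fold, with 15 false calls. DESeq2 recovered 73 and 94 with 24 false calls. The list test found the changed list and called 0 of 40 unchanged lists of 20 genes. Simulated genes varied independently, so this could not show false list calls that arise when members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out of the comparison, and genes below the count filter were left out of the tests only.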

Results

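Gene expression was measured by bulk RNA sequencing in endothelial cells sorted by flow cytometry from the mouse placental labyrinth, the zone where maternal and fetal blood exchange solutes. The 3 knockout libraries were taken to come from embryos with floxed Dnmt3a alleles and a Cdh5-Cre transgene, which places the recombinase in endothelium. The 3 control libraries, titled wild type, were taken to come from embryos with the floxed alleles alone, the other genotype of the design text, since no label ties a title to a genotype. The study title names the spatial zonation of the placental vasculature and its epigenetic specification, so the comparison of knockout with control asks which genes respond when endothelial Dnmt3a is targeted. On this reading the knockout libraries differ from control by the Cre transgene as well as by Dnmt3a. Neither group holds the transgene without the floxed alleles, so their effects cannot be told apart, and genotype below covers both. Control replicates 1, 2 and 3 held 42322482, 43442767 and 44897210 counts, and knockout replicates 1, 2 and 3 held 42393816, 40206223 and 42530046. Of 55536 genes in the count table, 16748 had enough counts to be tested. Nothing in the labels says which animals or litters the libraries came from, so each p-value measures the spread between these samples.

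Endothelial transcripts were abundant in both groups. Pecam1, an endothelial adhesion molecule, had a mean of 3484 CPM (counts-per-million) in control and 3578 in knockout, and Kdr, the main VEGF receptor, had 2597 and 2757. Across tested genes, log2 CPM correlated at 0.991 to 0.993 between control libraries, 0.990 to 0.992 between knockout libraries and 0.989 to 0.992 between groups, where genes are not independent replicates. Xist, expressed from the inactive X chromosome, had 64.5, 68.4 and 50.2 CPM in control and 0.0963, 66.2 and 52.1 CPM in knockout replicates 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together held 10069 counts in knockout replicate 1 and 0 or 1 in each other library.

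Genes on chromosome 7 lay lower in the knockout libraries as a group. The median deviation of its genes was 0.05, 0.04 and 0.09 (log2) in control replicates 1, 2 and 3 and 0.01, -0.12 and -0.06 in knockout replicates 1, 2 and 3. The difference in means was -0.12, against -0.01 to 0.02 for the other autosomes, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 samples allow. Chromosome 7 held 7.77% of the tested genes and 11 of the 37 genes that fell (Fisher's exact test p = 7.73e-05, genes not being independent), and 2 genes that rose. This chromosome was picked after the values were seen, and neither p is adjusted for that choice among the chromosomes. Without knockout replicate 2, which had the lowest median, 10 of 32 lower genes were on this chromosome.

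**Figure D1:**
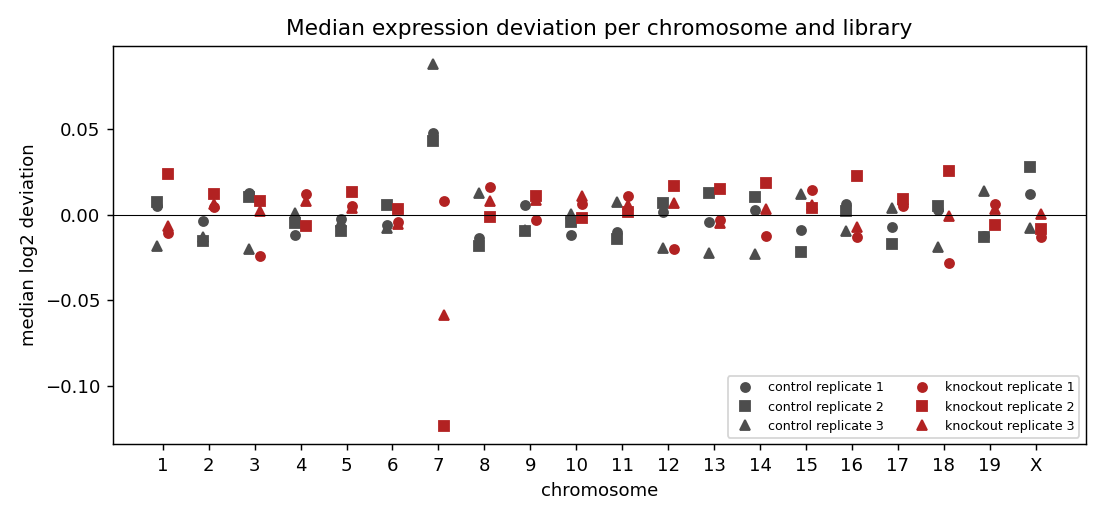
Median log2 deviation of gene expression from the mean of all libraries (vertical axis) for each chromosome (horizontal axis), with 1 point per library. The chromosome 7 medians run from -0.12 in knockout replicate 2 to 0.09 in control replicate 3, while the other chromosomes stay between -0.03 and 0.03.

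Transcripts of the targeted gene, Dnmt3a (ENSMUSG00000020661), which encodes a de novo DNA methyltransferase, fell to 49.5% of its control level. Its abundance was 175, 174 and 169 CPM in control replicates 1, 2 and 3 and 83.4, 96.1 and 77.3 CPM in knockout replicates 1, 2 and 3. The means were 173 ± 3.01 CPM in control and 85.6 ± 9.59 CPM in knockout (SD, n = 3), and the edgeR log2 fold change was -1.01 (SE 0.08, adjusted p = 0.0004). Counts covered the whole gene, and the deleted exons are not given in the sources used here, so these values do not measure the deletion itself.

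**Figure D2:**
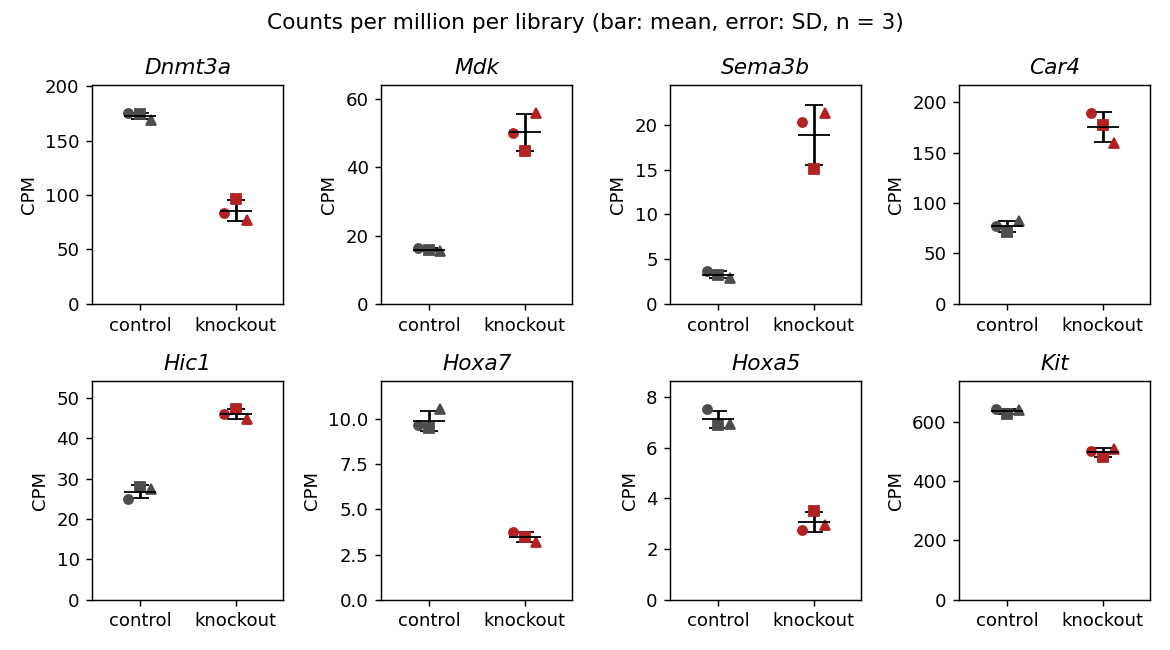
CPM (vertical axis, from 0) of Dnmt3a and 7 other genes in each library, with the mean as a bar and the SD as error (n = 3 per group); circles, squares and triangles are replicates 1, 2 and 3. Knockout libraries lie below every control library for Dnmt3a, Hoxa7, Hoxa5 and Kit and above every control library for Mdk, Sema3b, Car4 and Hic1.

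Secreted signals, a capillary enzyme and a neurotrophin receptor were among the genes that rose most firmly in the knockout. Mdk (ENSMUSG00000027239), the heparin-binding growth factor midkine, rose 3.17-fold, from 15.8 ± 0.459 to 50.1 ± 5.44 CPM (SD, n = 3; log2 fold change 1.66, SE 0.09, adjusted p = 4.6e-05). Sema3b (ENSMUSG00000057969), a secreted semaphorin, rose 5.76-fold, from 3.28 ± 0.388 to 18.9 ± 3.33 CPM (log2 fold change 2.53, SE 0.15, adjusted p = 0.000107). Car4 (ENSMUSG00000000805), a membrane-bound carbonic anhydrase of capillary endothelium, rose 2.27-fold, from 77.0 ± 5.44 to 175 ± 15 CPM (log2 fold change 1.18, SE 0.08, adjusted p = 0.000127). Ntrk2, the receptor for brain-derived neurotrophic factor, rose 5.25-fold from 0.893 CPM, Hic1, a transcriptional repressor, rose 1.72-fold from 26.8 CPM, and Pmaip1, a pro-apoptotic p53 target, rose 2.93-fold from 3.75 CPM. Lrmp rose 2.58-fold, and Pcdhga12 rose 1.97-fold, although gamma protocadherins share exons, so the counts of a single member are uncertain. The largest increases among the remaining moderately expressed genes were those of Fbp2, a fructose bisphosphatase (log2 fold change 2.05), Ccdc184 (1.70), Clic6 (1.67) and Mal (1.53). By the rule that selected them, all of these genes were higher in 3 of 3 knockout libraries than in any control library. Without control replicate 2 the calls of Ccdc184 and Fbp2 were lost (adjusted p 0.0858 and 0.0862), as they were without knockout replicate 3 (0.0718 and 0.0660), and that of Fbp2 also without control replicate 1 (0.0599).

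More genes rose than fell. At an adjusted p under 0.05, edgeR called 142 genes changed, 105 of them higher and 37 lower in the knockout, and 32 of the higher and 9 of the lower genes changed at least 2-fold. The median log2 fold change was 0.62 among genes that rose and -0.63 among genes that fell, and -0.0022 over all tested genes. An unadjusted p under 0.05 was reached by 1824 genes, against 837 expected by chance. DESeq2 called 501 genes, 140 of the 142 among them, and limma voom called 392, 141 of the 142 among them. The edgeR count was 44 without control replicate 1, 25 without control replicate 2 and 25 without knockout replicate 3.

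**Figure D3:**
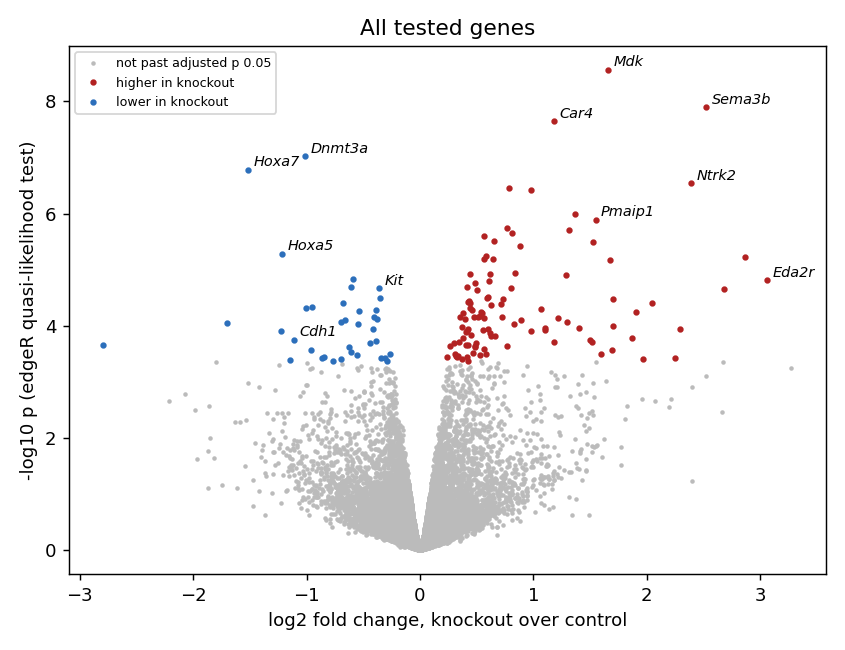
Log2 fold change of knockout over control (horizontal axis) against -log10 of the unadjusted edgeR p-value (vertical axis) for each of the 16748 tested genes. Red marks the 105 genes that rose and blue the 37 that fell at an adjusted p under 0.05, with Mdk and Sema3b uppermost on the right and Dnmt3a and Hoxa7 on the left.

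Homeobox genes, which set positional identity in the embryo, were among the genes that fell. Hoxa7 (ENSMUSG00000038236) fell from 9.91 ± 0.559 to 3.46 ± 0.287 CPM (SD, n = 3; log2 fold change -1.52, SE 0.12, adjusted p = 0.000557), and Hoxa5 fell from 7.11 to 3.06 CPM (log2 fold change -1.21, adjusted p = 0.00481). Hoxd9 fell from 2.07 to 0.634 CPM (log2 fold change -1.70, adjusted p = 0.0199). Of 22 measured Hox genes, 0 rose and 3 fell over all genes tested, and 1 rose and 8 fell when adjusted over the list alone. The list median was -0.20 (log2), and the list was called lower by camera (adjusted p = 8.00e-05), a call lost at adjusted p = 0.352 with an estimated correlation. Evx1, a homeobox gene outside the list, fell from 14.1 to 6.03 CPM (log2 fold change -1.22, adjusted p = 0.0232). Hoxa7 and Hoxa5 kept their calls with each library left out (adjusted p 0.000906 to 0.0394), whereas Hoxd9 lost its call without control replicate 2 (0.0991), knockout replicate 2 (0.0510) or knockout replicate 3 (0.118). With 1 library left out, Evx1 kept its call only without knockout replicate 2 (0.00449), the other values being 0.0511 to 0.118.

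The other named genes that fell included receptors and enzymes. Kit, the stem cell factor receptor, fell from 637 ± 8.84 to 498 ± 14.8 CPM (log2 fold change -0.36, adjusted p = 0.0102), and Hif3a, a hypoxia-inducible factor subunit, fell from 301 ± 10.1 to 236 ± 5.51 CPM (log2 fold change -0.35, adjusted p = 0.0133). Ptprs, a receptor tyrosine phosphatase, fell from 106 to 69.3 CPM, Sema5a, a transmembrane semaphorin, fell from 21.3 to 14.2 CPM, and B3gnt9, a glycosyltransferase, fell from 10.8 to 6.78 CPM. The largest remaining decreases were those of Cdh1 (log2 fold change -1.11), the collagen prolyl hydroxylase subunit P4ha3 (7.89 to 3.94 CPM) and Pga5 (-0.95). Each of these was lower in 3 of 3 knockout libraries than in any control library, which the naming rule requires. All 8 lost their calls without control replicate 2 or without knockout replicate 3 (adjusted p 0.0634 to 0.164), Kit, Hif3a, B3gnt9, P4ha3 and Cdh1 also without control replicate 1 (0.0571 to 0.101), and Cdh1 also without knockout replicate 2 (0.0773).

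Capillary and tip cell genes lay toward higher expression, while endothelial identity genes as a group were not called by camera. Of 20 measured capillary markers, 4 rose and 0 fell over all genes tested (Car4, Cd300lg, Rgcc and Sparcl1), and 5 rose and 2 fell when adjusted over the list alone. Cd300lg, a receptor of capillary and venular endothelium, rose from 152 to 207 CPM, Rgcc from 234 to 303 CPM and Sparcl1 from 1900.5 to 2291.3 CPM. The capillary list had a median of 0.11 and was called higher (adjusted p = 0.0107; adjusted p = 0.572 with an estimated correlation). Of 23 tip cell and sprouting genes, 1 rose and 0 fell, with 6 higher and 0 lower adjusted over the list alone. Ramp3, a receptor activity-modifying protein, rose from 178 to 221 CPM, while Apln had a log2 fold change of 0.54 (adjusted p = 0.130) and Nos3 of 0.19 (0.116). The tip cell list had a median of 0.13 and was called higher (adjusted p = 0.00067; adjusted p = 0.572 with an estimated correlation). The capillary list lost its call without control replicate 1 (adjusted p 0.145), knockout replicate 1 (0.0538), knockout replicate 3 (0.0591) or with the replicate block (0.0565), and its higher members numbered 1 without control replicate 1, control replicate 2 or knockout replicate 3. Car4 was past the threshold each time, the calls of Cd300lg, Rgcc and Sparcl1 were lost in those 3 settings (adjusted p 0.0703 to 0.184), that of Sparcl1 also without knockout replicate 1 (0.0877), and that of Ramp3 with any library left out except control replicate 3 (0.0635 to 0.197).

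**Figure D4:**
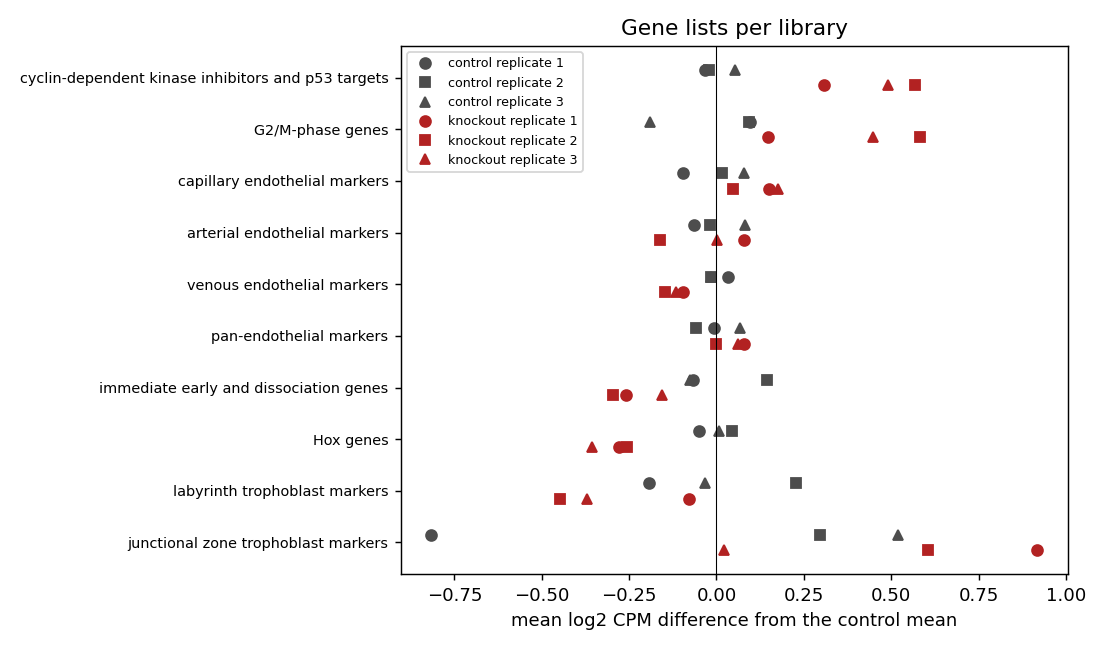
Mean log2 CPM difference from the control mean (horizontal axis) for 10 of the gene lists (vertical axis), 1 point per library. The p53 target list lies between 0.31 and 0.57 in the knockout libraries and between -0.03 and 0.05 in control, and the junctional zone trophoblast list spreads from -0.82 to 0.52 within control.

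Arterial and venous markers were not called as groups by camera, although each held changed genes. Of 30 arterial markers, Unc5b, a netrin receptor, rose from 63.9 to 85.5 CPM (adjusted p = 0.0496) and Eln, which encodes elastin, fell from 753 ± 84.6 to 415 ± 115 CPM (log2 fold change -0.86, adjusted p = 0.0470), with 6 higher and 3 lower adjusted over the list alone. The arterial median was 0.06, its mean was -0.02, and its test pointed up without a call (adjusted p = 0.267). Of 19 venous markers, 1 rose and 0 fell, Icam1, a leukocyte adhesion receptor, going from 223 to 290 CPM (log2 fold change 0.38, adjusted p = 0.0164), with 3 higher and 5 lower adjusted over the list alone. The venous list was not called (median -0.05, adjusted p = 0.267). Of 20 pan-endothelial markers, 1 rose and 0 fell, Mmrn2 going from 333 to 473 CPM (log2 fold change 0.51, adjusted p = 0.0105), with 1 higher and 1 lower adjusted over the list alone (median 0.04, list adjusted p = 0.225). Cldn5, a tight junction protein, had a log2 fold change of -0.24 (adjusted p = 0.115). The call of Unc5b was lost with any library left out (adjusted p 0.0539 to 0.189), those of Eln, Icam1 and Mmrn2 without control replicate 1, control replicate 2 or knockout replicate 3 (adjusted p 0.0516 to 0.202), and that of Eln also without control replicate 3 (0.0649). Among genes with a mean of at least 5 CPM, the calls of Eln and Unc5b were also lost (0.0538 and 0.0626). Without control replicate 3 the arterial and pan-endothelial lists were called higher (adjusted p 0.0238 and 0.0318).

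Genes of alternative endothelial fates gave few calls. Of 14 haemogenic and progenitor genes, Adgrg1, an adhesion G protein-coupled receptor, rose from 68.9 to 96.3 CPM (adjusted p = 0.00918) and Kit fell, with 1 higher and 1 lower adjusted over the list alone (list adjusted p = 0.826). Of 14 lymphatic markers, 1 rose and 0 fell, Tbx1, a T-box factor, going from 0.160 to 0.636 CPM (adjusted p = 0.0480), with 1 higher and 3 lower adjusted over the list alone (list adjusted p = 0.483). Of 18 endothelial-to-mesenchymal transition genes, 0 rose and 1 fell, Mmp2, a matrix metalloproteinase, going from 55.3 to 38.0 CPM, with 0 higher and 5 lower adjusted over the list alone. That list had a median of -0.07 and was called lower (adjusted p = 0.00569; adjusted p = 0.525 with an estimated correlation). Of its 18 members, 11 also stand in other lists, Mmp2 among the matrix genes, and the fibroblast markers were called lower as well (median -0.14, adjusted p = 0.0486; adjusted p = 0.731 with an estimated correlation). The transition list lost its call without control replicate 2 (0.0558). The calls of Adgrg1 were lost without control replicate 2 (0.0627) or knockout replicate 3 (0.0673), those of Kit and Mmp2 in these settings and without control replicate 1 (0.0599 to 0.108), and that of Tbx1 with any library left out (0.101 to 0.194).

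Targets of p53 and cyclin-dependent kinase inhibitors lay higher as a group. Of 21 measured members, 8 rose and 0 fell over all genes tested, and 13 rose and 1 fell when adjusted over the list alone. Eda2r, a receptor of the tumour necrosis factor family, rose 8.34-fold from 0.795 to 6.65 CPM (adjusted p = 0.0089), Pmaip1 rose from 3.75 to 11.0 CPM, Gtse1, a p53-binding protein of G2 phase, from 4.23 to 9.86 CPM, and Cdkn1a, the p21 inhibitor, from 260 to 342 CPM (adjusted p = 0.0183). The list had a median of 0.29 and was called higher (adjusted p = 1.01e-07; adjusted p = 0.525 with an estimated correlation), and the mean over members was 0.31, 0.57 and 0.49 (log2) above control in knockout replicates 1, 2 and 3. Its higher members numbered 3, 1 and 5 without control replicates 1, 2 and 3, and 10, 8 and 1 without knockout replicates 1, 2 and 3. Only the call of Pmaip1 among these 4 genes held with each library left out (adjusted p at most 0.0175). Those of Eda2r, Gtse1 and Cdkn1a were lost without control replicate 2 or knockout replicate 3 (0.0561 to 0.108), that of Cdkn1a also without control replicate 1 (0.0981), and that of Gtse1 also without control replicate 3 (0.0541).

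Mitotic genes also lay higher as a group, with single members short of the threshold. All 25 measured G2/M-phase genes had positive fold changes (median 0.41), and the list was called higher (adjusted p = 1.26e-12; adjusted p = 0.525 with an estimated correlation). By edgeR, 0 members passed over all genes tested, 21 were higher and 0 lower when adjusted over the list alone, 21 had an unadjusted p under 0.05, and DESeq2 and limma voom passed 3 and 0. Plk1, a mitotic kinase, had a log2 fold change of 0.41 (adjusted p = 0.130) and Ccna2, cyclin A2, of 0.46 (0.193). The library means were 0.15, 0.58 and 0.45 in knockout replicates 1, 2 and 3 against 0.10, 0.09 and -0.19 in control replicates 1, 2 and 3. Without knockout replicate 1, 2 members passed, Ccna2 among them (adjusted p = 0.0330). S-phase genes were not called (25 measured, median -0.01, adjusted p = 0.635), and 0 of them passed by edgeR, with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom.

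Immediate early genes, which respond within minutes to growth factors or handling, lay lower as a group. Of 24 measured members, 0 rose and 2 fell over all genes tested, and 0 rose and 11 fell when adjusted over the list alone. Egr1, a zinc finger transcription factor, fell from 580 ± 98.4 to 375 ± 39.0 CPM (log2 fold change -0.63, adjusted p = 0.0349), and Egr2 fell from 23.7 to 13.2 CPM (-0.85, 0.0457). The list median was -0.20, and the list was called lower (adjusted p = 1.27e-06; adjusted p = 0.525 with an estimated correlation). Of 19 unfolded protein response genes, 1 rose and 0 fell, Sesn2, a stress-induced sestrin that the p53 list also holds, going from 27.8 to 42.7 CPM, with 2 higher and 0 lower adjusted over the list alone (median 0.02, list adjusted p = 0.232). With 1 library left out, Egr1 kept its call only without control replicate 3 (0.0197) and Egr2 only without control replicate 1 (0.0322), the other values being 0.0616 to 0.169, and both calls were lost among genes with a mean of at least 5 CPM (0.0525 and 0.0620), that of Egr2 also with voom (0.0620). The call of Sesn2 was lost without control replicate 1, 2 or 3 or knockout replicate 3 (0.0508 to 0.119), and the unfolded protein response list was called without control replicate 3 (0.0238).

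Genes that DNA methylation is known to silence held no member past the threshold by edgeR over all libraries. Of 52 listed germline genes, 17 were measured and 0 passed by edgeR, with 1 higher and 0 lower adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2 or voom. Tex15, a meiotic gene, had a log2 fold change of 2.20 (adjusted p = 0.124) and read 5.73 and 6.63 CPM in knockout replicates 1 and 3 but 1.003 CPM in knockout replicate 2, against 0.719 to 1.31 CPM in control. Stk31, a testis kinase, showed the same pattern, with 7.51, 2.03 and 6.04 CPM in knockout replicates 1, 2 and 3. The germline list had a median of 0.11 and was not called (adjusted p = 0.179; adjusted p = 0.525 with an estimated correlation). With the preset correlation it was called higher without knockout replicate 2 (0.000384) or without control replicate 1 (0.0060), 2 (0.000903) or 3 (0.0409). Without knockout replicate 2, 3 members passed, Tex15 (0.00196) and Stk31 (0.0260) among them. Imprinted genes were not called by camera (49 measured, median -0.04, adjusted p = 0.232) but were called lower by fry (adjusted p = 0.0426), with 0 past the threshold by edgeR, 10 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. The imprinted list was not tested without the genes of chromosome 7, which lay lower as a group. Cdkn1c, an imprinted kinase inhibitor, had a log2 fold change of -0.23 (adjusted p = 0.283). The other DNA methylation machinery genes were not called (22 measured, adjusted p = 0.802), with 0 members past by edgeR, 1 higher and 0 lower adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. Dnmt3b, the paralog of Dnmt3a, had a log2 fold change of 0.35 (adjusted p = 0.0892).

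Signalling and matrix groups held few changed genes. Of 27 BMP and TGF-beta pathway genes, 2 rose and 0 fell, Inhbb, an activin subunit, going from 2.34 to 5.02 CPM (adjusted p = 0.0231) and Tgfb3 from 13.9 to 20.4 CPM (0.0230), with 2 higher and 2 lower adjusted over the list alone (median -0.01, list adjusted p = 0.635). Of 28 basement membrane and matrix genes, 1 rose and 2 fell, Lama4, a laminin chain of endothelial basement membrane, going from 602 to 811 CPM while Mmp2 and Eln fell, with 8 higher and 5 lower adjusted over the list alone. The matrix list was not called (median 0.05, mean -0.04, adjusted p = 0.293). Of 23 vascular guidance genes, 1 rose (Unc5b) and 0 fell, with 6 higher and 2 lower adjusted over the list alone (median 0.01, mean -0.02, list adjusted p = 0.299, and 0.0495 at a mean of at least 5 CPM). The calls of Tgfb3, Inhbb, Lama4, Mmp2, Eln and Unc5b were lost without control replicate 1, control replicate 2 or knockout replicate 3 (adjusted p 0.0599 to 0.202), and those of Tgfb3 and Unc5b also without knockout replicate 1 (0.0529 and 0.0539). Unc5b also lost its call without control replicate 3 (0.0547) or knockout replicate 2 (0.0752), Eln without control replicate 3 (0.0649), and both among genes with a mean of at least 5 CPM (0.0626 and 0.0538).

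Leukocyte adhesion, antigen presentation and interferon genes pointed in different directions. Of 21 leukocyte adhesion and inflammation genes, 1 rose (Icam1) and 0 fell, with 5 higher and 0 lower adjusted over the list alone, and the list was called higher (median 0.23, adjusted p = 0.00679; adjusted p = 0.525 with an estimated correlation). Csf1, the macrophage growth factor, had a log2 fold change of 0.51 (adjusted p = 0.0772; 0.0155 without knockout replicate 1). The MHC class I list was called higher (18 measured, median 0.14, adjusted p = 0.0107; adjusted p = 0.730 with an estimated correlation), with 0 members past by edgeR, 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. H2-K1 had a log2 fold change of 0.51 (adjusted p = 0.138), uncertain because its reads can be shared with near-identical class I paralogs, and passed without knockout replicate 1 (0.0343). The interferon response list was called lower (30 measured, median -0.14, adjusted p = 0.00586; adjusted p = 0.731 with an estimated correlation), with 0 members past by edgeR, 1 higher and 2 lower adjusted over the list alone, 13 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by voom. Ifitm3 had a log2 fold change of -0.42 (0.133) and Cxcl10 of 0.73 (0.111; 0.0205 without knockout replicate 1). The MHC class I call was lost without control replicate 2 (0.254) or knockout replicate 3 (0.174), and the interferon call without control replicate 1 (0.517) or knockout replicate 1 (0.125). Icam1 lost its call without control replicate 1, control replicate 2 or knockout replicate 3 (0.0885 to 0.108).

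Transcripts of trophoblast, the neighbouring epithelium of the labyrinth, were present in every library. Prl3b1, placental lactogen II, had 926 ± 294 CPM in control and 955 ± 158 CPM in knockout (SD, n = 3), and Ctsq, a trophoblast cathepsin, had 467 and 487 CPM, both values uncertain because each belongs to a family of similar genes. Of 24 labyrinth trophoblast markers, 0 rose and 1 fell, Cdh1, which encodes E-cadherin, going from 9.66 to 4.46 CPM (adjusted p = 0.0298), with 0 higher and 3 lower adjusted over the list alone. Epcam, an epithelial adhesion molecule, had a log2 fold change of -0.90 (adjusted p = 0.139; 0.0190 without knockout replicate 1). The labyrinth list had a median of -0.25 and was called lower (adjusted p = 0.000908; adjusted p = 0.572 with an estimated correlation). Of its 24 members, 18 had negative and 6 positive fold changes. The most abundant ones, Ly6e (1225 CPM in control and 1295 in knockout), Ctsq and Lepr (214 and 218), were not lower. The junctional zone list was called higher (33 measured, median 0.13, adjusted p = 0.0317; adjusted p = 0.766 with an estimated correlation), with 0 members past by edgeR, 0 adjusted over the list alone, 7 at an unadjusted p under 0.05 and 0 by DESeq2 or voom, and its library means ran from -0.82 to 0.52 within control. Without control replicate 1 the junctional zone list pointed down (adjusted p 0.950), and its call was also lost without knockout replicate 1 (0.628) or knockout replicate 2 (0.0602), or with the replicate block (0.156). The labyrinth call was lost without control replicate 2 (0.0782), and that of Cdh1 without control replicate 1 (0.101), control replicate 2 (0.151), knockout replicate 2 (0.0773) or knockout replicate 3 (0.164).

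Fibroblast and erythroid markers lay lower as groups. Col3a1 and Col1a1, the most abundant fibrillar collagens, had 241 and 187 CPM in control and 206 and 176 CPM in knockout. The fibroblast list was called lower (21 measured, median -0.14, adjusted p = 0.0486; adjusted p = 0.731 with an estimated correlation), with 0 members past by edgeR, 0 higher and 3 lower adjusted over the list alone, 4 at an unadjusted p under 0.05 and 3 each by DESeq2 and voom. The erythroid list was called lower (16 measured, median -0.36, adjusted p = 0.00263; adjusted p = 0.525 with an estimated correlation), with 0 members past by edgeR, 0 higher and 1 lower adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by voom. Hbb-bs, an adult beta-globin gene with a near-identical paralog, had 53.2 ± 12.7 and 43.0 ± 16.5 CPM (SD, n = 3). The fibroblast call was lost without control replicate 1 (0.0966), control replicate 2 (0.487), knockout replicate 2 (0.160) or knockout replicate 3 (0.159), with RLE size factors (0.0505), a prior count of 0.5 (0.0513), a mean of at least 5 CPM (0.0553) or the replicate block (0.0596), and the erythroid call without knockout replicate 2 (0.112).

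Further pathways and cell types gave no calls by edgeR and camera over all libraries. With the imprinted, germline, methylation machinery and S-phase lists described above, 22 lists had 0 members past the threshold by edgeR and no list call by camera (adjusted p 0.0796 to 0.863), with 88 of their 441 members at an unadjusted p under 0.05, 16 past by DESeq2 and 8 by voom. They cover Notch, Wnt and VEGF signalling, Polycomb repressors, endothelial transcription factors, glycolysis and hypoxia, solute transporters, cholesterol synthesis, haemostasis and mitochondrially encoded genes. They also cover markers of pericytes and smooth muscle, decidual stroma, macrophages, lymphocytes and natural killer cells, neutrophils, megakaryocytes and yolk sac, and sex-linked genes. Jag1, a Notch ligand, had a log2 fold change of 0.18 (adjusted p = 0.204). Acta2, the smooth muscle actin, had 120 CPM in control and 105 CPM in knockout, and Csf1r, the macrophage receptor, had 20.05 and 19.57 CPM. Calls appeared for the sex-linked and lymphocyte lists without knockout replicate 3 (adjusted p 0.0156 and 0.0225) and for the yolk sac list without knockout replicate 1 (0.0471), and for the VEGF list at a mean of at least 5 CPM (0.0369). Of 45 lists tested, 14 were called with the preset correlation, 7 higher and 7 lower. With an estimated correlation 0 were called, and 2 lists had an unadjusted p under 0.05. The directional test of fry called 3, the Hox list lower (adjusted p = 0.00402), the p53 list higher (0.0426) and the imprinted list lower (0.0426). Its mixed test called 27 of the 45. Lists without a camera call were among these, such as the macrophage (adjusted p = 0.000139), venous (0.00262) and pan-endothelial lists (0.00612). The median, mean and test differed in sign for 8 lists, which were the arterial, guidance, matrix, methylation machinery, S-phase, haemostasis, decidual and neutrophil lists.

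The deposited comparison by the authors named nearly the same genes as edgeR plus a further set. Their table held 15304 genes, of which 480 had an adjusted p under 0.05, 303 higher and 177 lower in the knockout. It called 141 of the 142 genes that edgeR called, the exception being Epha5, an ephrin receptor named after its values were seen. All 479 called genes that were also tested by edgeR had the same sign in both. In the authors' table Mdk had a log2 fold change of 1.66, Sema3b of 2.52, Car4 of 1.18, Dnmt3a of -1.02 and Hoxa7 of -1.52. Genes called there and not by edgeR had a median edgeR adjusted p of 0.103. DESeq2 run on the deposited counts called 501 genes, 474 of them in common with the authors' table. Log2 fold changes of edgeR and of the authors' table correlated at 0.99999 across genes (Pearson), both coming from the same counts.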

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

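The test of a short segment of chromosome 7 and the test of immediate early genes as a sign of handling stress were chosen after the results were seen. The Y-linked genes and Afp were too sparse across libraries to be tested, and drew attention because their counts in the knockout libraries exceeded those in control. Ddx3y had 4680 counts over the knockout libraries, Eif2s3y had 2279, Uty had 1610 and Kdm5d had 1500, all in knockout replicate 1, while each had 0 to 2 counts over the 3 control libraries. Afp, the yolk sac and fetal liver protein alpha-fetoprotein, had 2186 counts over the knockout libraries, 2180 of them in knockout replicate 3, and 241 over the control libraries, 226 of them in control replicate 1.

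Chromosome 7 genes lay lower in the knockout libraries, with a difference in medians of -0.12 (log2) and 11 of the 37 genes that fell. Bias from GC content and transcript length is argued against, since removing both trends left the difference at -0.118, against -0.0021 to 0.017 for the other autosomes. A short segment carried with the cross is argued against as well, since 10 of 10 consecutive blocks lay below the 10th percentile of 111 blocks on other autosomes, with the later blocks lower (-0.14 to -0.20) than the earlier ones (-0.03 to -0.08). A dosage difference of the whole chromosome in part of the cells cannot be told apart from a shift carried by part of the genes. The ratio of interquartile ranges was 1.19, between the bounds set for either. Whether later and earlier blocks differ beyond the spread of blocks was not tested, and neither was a longer segment. An effect of the genotype, the Cre transgene included, may also apply and stays open, since the knockout and control groups are what the design compares.

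The p53 target list lay higher in the knockout libraries, with a median of 0.29 (log2) and 8 of 21 members that rose, and its calls here use the preset correlation (adjusted p = 0.525 with an estimated correlation over all libraries). The sex of the embryos behind knockout replicate 1 is argued against as the cause, since the median was 0.39 without that library and the list was called (adjusted p = 1.17e-08). Immediate early genes gave no sign of more handling stress in the knockout, because their median was -0.20 and not above 0. They were already known to be lower when this test was chosen, so it cannot exclude a handling difference. The chromosome 7 shift of knockout replicate 2 alone is argued against as the whole cause, since the list was called without that library (adjusted p = 7.12e-06). The median was then 0.24, which cleared its bound by a small margin only. A shift of chromosome 7 in all knockout libraries was not tested this way. Chromosome 7 medians of knockout replicates 1 and 3 (0.01 and -0.06) also lay below every control library. A response to the genotype, either to loss of Dnmt3a or to the Cre transgene, may account for the pattern. It remains a hypothesis found on these data, with single members past the threshold numbering 1 of 21 without knockout replicate 3.

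Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real grouping gave 142 changed genes, 105 higher and 37 lower, and the highest of the other splits gave 2 changed genes, and at most 2 in a single direction. In each of these 3 counts, 1 of 10 splits, the real one, gave a result as large. For the gene lists the real grouping called 14 and the highest other split called 15, so that 3 of 10 splits called at least 14. The split with 15 set control replicate 1 and knockout replicates 2 and 3 against the rest. The number of list calls with the preset correlation therefore does not set the real grouping apart from others.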

How the results depend on the processing

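The chromosome 7, GC content and length settings, and list members with a library left out, were chosen after the data were seen. Dnmt3a kept its direction and call in all 12 settings (log2 fold change -1.10 to -0.95 with libraries left out). All 24 genes named by rank kept their sign wherever measured. They passed with RLE, DESeq2, voom, no filter and the replicate block, as did the 23 measured at a mean CPM of at least 5. Without control replicate 2 or knockout replicate 3, 10 of 12 higher and 3 of 12 lower genes passed, and without control replicate 1, 11 and 6. The replicate block gave 126 changed genes, 98 of the 142 among them, but deviations of same-numbered libraries correlated at -0.30, 0.21 and -0.19 across genes, so the numbers do not pair them. Control replicate 3 with knockout replicate 1 and control replicate 1 with knockout replicate 3 correlated at 0.35 and 0.34, a structure across groups whose source was not tested. In the replicate block 9 called list members lost their calls (Egr1, Eln, Gtse1, Hoxd9, Inhbb, Ramp3, Sparcl1, Tbx1 and Unc5b; adjusted p 0.0504 to 0.0792), and 4 did so at a mean CPM of at least 5 (Egr1, Egr2, Eln and Unc5b; 0.0525 to 0.0626).

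Changed, higher and lower genes numbered 501, 319 and 182 with DESeq2, 392, 260 and 132 with voom, and 393, 269 and 124 with no filter. They numbered 41, 32 and 9 at an absolute log2 fold change of at least 1, by construction. With 1 library left out they ranged from 25 to 191, 22 to 134 and 3 to 57. The cause was not tested for the other settings or the left-out libraries. Called lists numbered 0 with an estimated correlation and 3 with the directional test of fry, which tests another hypothesis, and 11 to 18 with libraries left out. The replicate block called 11 and ended the calls of the capillary (0.0565), junctional zone (0.156) and fibroblast lists (0.0596). The junctional zone trophoblast list pointed down without control replicate 1 (adjusted p 0.950; range with libraries left out 0.000498 to 0.950), and the cause was not tested. With chromosome 7 left out, 148 genes were called, and 147 with GC content and length offsets. Genes below the count filter were not tested, and what depth limits among tested genes was not measured.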

Other observations

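The elastic fibre list and its tests were chosen after the results were seen, with the bounds of the cell type tests tightened after a first look. Elastic fibre genes build the recoil of vessel walls. Of 19 measured members, 15 had a negative fold change, 1 fell (Eln) and 0 rose, and the median was -0.25 (log2), a value not tested as a list. Mfap5, a microfibril protein, had a log2 fold change of -1.28 (adjusted p = 0.0885), Lox, the crosslinking enzyme, of -0.64 (0.141) and Fbln5, an elastin-binding fibulin, of -0.50 (0.114). The mean over members was -0.09, -0.55 and -0.51 in knockout replicates 1, 2 and 3 against -0.02, 0.12 and -0.10 in control replicates 1, 2 and 3, so that of knockout replicate 1 lay within the control range. With 1 library left out the median ranged from -0.46 to -0.14, the call of Eln was lost without control replicate 1, 2 or 3 or knockout replicate 3 (adjusted p 0.0649 to 0.202), and that of Fbln5 appeared without knockout replicate 1 (0.00775).

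A lower share of another cell type could lower these genes. Fewer arterial endothelial cells as a whole are argued against by the other 25 arterial markers, whose lower quartile was 0.00117. With all 30 arterial markers it was -0.08, and both lay above every value of the elastic fibre median (-0.46 to -0.14). Loss of a small arterial subset that makes elastic fibres need not move these markers, so it stays open. Fewer pericytes and smooth muscle cells cannot be told apart from a change within cells, because the lower quartile of their markers was -0.199, inside the range of that median. Fewer fibroblasts stay open for the same reason, with a lower quartile of -0.224, and Acta2, Col3a1 and Col1a1 had 105, 206 and 176 CPM in the knockout. The sort on endothelial cells should deplete these types, but transcripts of their markers remained, as these values show. An effect of the genotype within endothelium stays open as well.

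Clustered protocadherins are adhesion molecules whose genes lie in arrays. Of 11 measured beta members, 10 had a negative fold change with a median of -0.62 (log2) and 0 passed by edgeR, and of 21 gamma members, 12 had a positive fold change with a median of 0.02, and 1 rose (Pcdhga12). Reads shared between members make single values uncertain, and no difference between the arrays was tested.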
